A study of Homo sapiens with 14 samples.

How the data were processed

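RNA from sorted GFP-bright LS174T and HepG2 cells carrying dnTCF4 or control plasmids was measured on 14 Affymetrix Gene ST arrays, 1 array per sample. Per the labels' protocols, total RNA was isolated with TRIzol and cleaned on RNeasy columns, 300 ng was labelled with the Affymetrix whole transcript kits, and HepG2 cells were grown on collagen I. The values are the authors' deposited probe set intensities on a linear scale, 33252 per array. The background correction, summary and normalization behind these intensities are not given in the sources used here. The arrays differ in median and quartiles, so they were not forced to 1 common distribution at this level. The values carry no detection call and no count, so depth is unknown and the number of arrays and the probe set's brightness limit precision. A probe set near the dim end understates a change, since background adds to both groups.

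Groups and replicate numbers were taken from the labels. There were 3 LS174T control, 3 LS174T dnTCF4, 4 HepG2 control and 4 HepG2 dnTCF4 arrays, and no pair of arrays held identical values. Gene names came from a table pairing probe sets with the platform's annotation, with older symbols updated through a RefSeq gene table of the assembly GRCh38.p14, which was used for names only. Of the probe sets, 21214 were listed in that table, 19460 with 1 symbol and 1754 with several, and 12038 were not listed and stay unnamed. Only probe sets with 1 symbol entered the analysis. For the 769 genes with several, the probe set with the highest mean log2 value over all arrays was used, which left 18417 genes. Among genes with several probe sets, probe sets were called in opposite directions for 1 gene in LS174T, 11 in HepG2, 2 in the difference and 50 in the comparison of controls. No coordinates are given, because the array's genome build is not named in the sources used here.

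Intensities were transformed as log2(intensity + 1) with no further normalization and no filter. Limma (version 3.58.1, R 4.3.3) was fitted with 1 mean per group over all 14 arrays, which share 1 estimate of the spread with 10 residual degrees of freedom, followed by plain eBayes. The contrasts were dnTCF4 against control in each line, the difference of these changes (LS174T minus HepG2), and LS174T control against HepG2 control. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes were called higher or lower. Overlap of the responses was tested with Fisher's exact test. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists of a contrast, with an estimated correlation and with fry as alternatives. The lists were Wnt target genes, Wnt pathway machinery, intestinal crypt and stem cell, enterocyte and colonocyte, goblet and secretory, pericentral hepatocyte, periportal hepatocyte, hepatocyte secreted proteins, bile acid metabolism, glucose metabolism, cholesterol synthesis, fatty acid synthesis, DNA replication, mitosis, p53 targets, ribosome biogenesis, BMP and TGF-beta response, interferon response, unfolded protein and amino acid stress, immediate early genes, and stromal, endothelial and immune markers. Some genes stand on more than 1 list, and list members without a probe set of their own were not measured.

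Design, lists, alternatives and the rule for naming genes were fixed before the data were examined. In each line the rule named TCF7L2, AXIN2, LGR5 and MYC, and the 6 largest rises and 6 largest falls among called genes whose arrays did not overlap, leaving out uncharacterized loci, small RNAs and olfactory receptors. From each list it named the 2 called members with the largest change (4 for the Wnt target, crypt, enterocyte and pericentral lists), or the 1 member with the smallest p where none was called. For the difference it named 6 genes in each direction, and for the controls 2 genes per cell type list. MIR30A, a small RNA the rule leaves out, was named after its values were seen. The steps were tested on simulated data with 200 of 18417 genes changed. At a 1.5-fold and a 2-fold change the fit recovered 46% and 87% of the changed genes for LS174T and 63% and 91% for HepG2, and 6.99% and 3.75% of its calls were false. Camera called the changed set and 0 of 20 unchanged sets. The simulated noise was independent between arrays and between genes. In the real data the HepG2 dnTCF4 arrays formed tight pairs (consensus correlation 0.801), so these rates do not carry over to the real data. The alternatives were quantile normalization, median centring, a filter at the 40th percentile of gene means, the mean of a gene's probe sets, all probe sets, each line alone, eBayes with trend and robust, array weights, a 1.5-fold minimum, the replicate number as a block, log2(intensity + 16), an unadjusted p under 0.01 for the overlap, and leaving out each array. Averaging the HepG2 pairs, using either pair alone, a random block of pairs, and gene-by-gene array weights were added after the data were seen. Figures were drawn with matplotlib 3.10.9.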

Results

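Gene expression was measured on 14 Affymetrix Gene ST arrays in 2 human cancer cell lines, LS174T from colon cancer and HepG2 from liver cancer. Cells were transiently transfected either with a vector expressing GFP and a dominant negative form of TCF4 (dnTCF4) or with control plasmids, and the brightest GFP cells were sorted 48 h later. TCF4 is the protein of TCF7L2, a transcription factor that binds beta-catenin at the end of the Wnt pathway, and the dominant negative form blocks that output. There were 3 control and 3 dnTCF4 arrays for LS174T and 4 of each for HepG2. The median probe set intensity per array lay between 301.985 in HepG2 control replicate 1 and 364.92 in HepG2 dnTCF4 replicate 2, and the number of arrays limits the precision of every value. The labels do not say whether replicates came from separate transfections, so p-values measure only the spread between these arrays, which may be technical. Log2 changes below are given ± SE, on the log2(intensity + 1) scale, with limma's adjusted p over 18417 genes. The SE rests on the spread shared by all groups, so spread among HepG2 arrays can also widen SEs and cost calls in LS174T.

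The first check concerned the expressed gene itself. In LS174T, the TCF7L2 probe set (7930537) rose from 3947 ± 140.3 to 11146 ± 544.1 intensity units (SD, n = 3 in each group), a log2 change of 1.497 ± 0.20 (limma adjusted p = 8.68e-05). In HepG2 it rose from 1594 ± 89.7 to 10206 ± 3265 (SD, n = 4 in each group), a log2 change of 2.62 ± 0.17 (limma adjusted p = 1.79e-07). Which part of the transcript this probe set reads was not analysed here, so vector and endogenous transcripts are not separated.

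**Figure D1:**
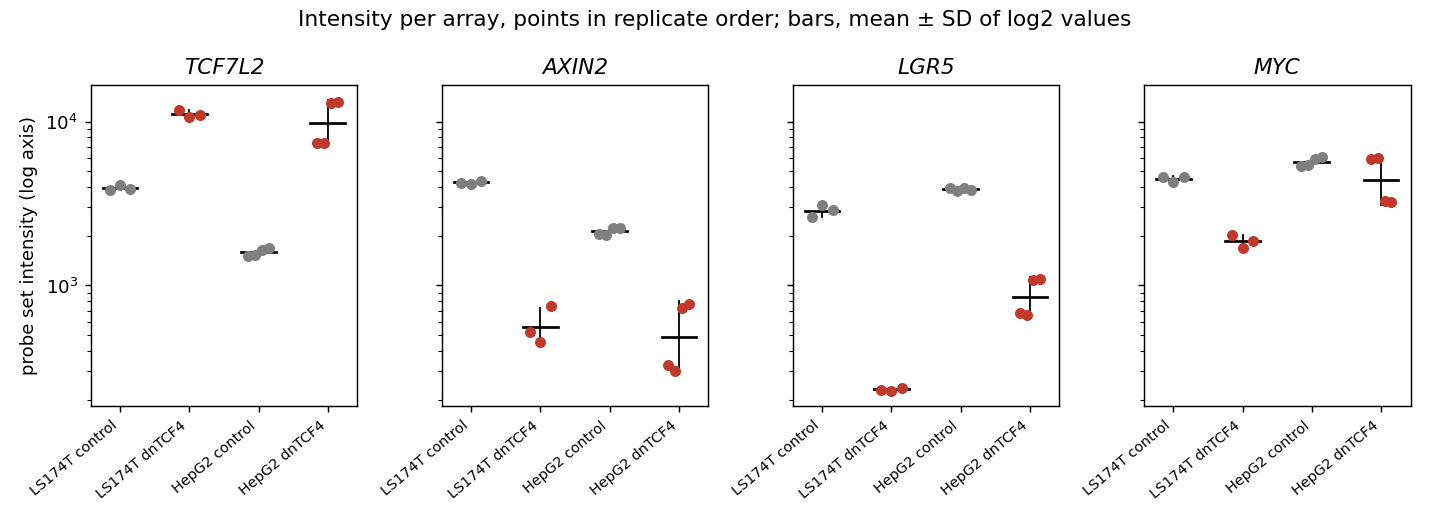
Probe set intensity (log axis) of TCF7L2, AXIN2, LGR5 and MYC on each of the 14 arrays, grouped by cell line and plasmid, with points in replicate order and bars for the mean and SD of the log2 values. TCF7L2 was higher and AXIN2 and LGR5 were lower on every dnTCF4 array than on every control array of the same line, while MYC in HepG2 changed by 0.14 in replicates 1 and 2 and by -0.88 in replicates 3 and 4 (log2).

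The comparison within LS174T asked which genes respond to TCF inhibition in colon cancer cells. The intestinal stem cell receptor LGR5 fell 12.2-fold, from 2860 ± 230.8 to 232 ± 5.69 intensity units (SD, n = 3), a log2 change of -3.61 ± 0.17 (limma adjusted p = 1.44e-08). AXIN2, a feedback inhibitor of the Wnt pathway and one of its standard readouts, fell 7.57-fold, a log2 change of -2.92 ± 0.31 (limma adjusted p = 1.55e-05). MYC fell by 1.27 ± 0.21 on the log2 scale (limma adjusted p = 0.000585), while the cyclin-dependent kinase inhibitor gene CDKN1A rose by 2.36 ± 0.15 (limma adjusted p = 2.11e-07). Genes of DNA replication, mitosis and ribosome biogenesis fell together, and genes of the unfolded protein and amino acid stress response rose.

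Among the Wnt target genes fixed before the data were examined, 8 of the 17 measured fell, none rose and 9 did not pass the test, with a mean log2 change of -0.79 (camera adjusted p = 0.000466). Besides LGR5 and AXIN2, the transcription factor gene LEF1 fell by 2.39 ± 0.16 (limma adjusted p = 2.31e-07) and the Wnt receptor ubiquitin ligase gene RNF43 fell by 1.57 ± 0.12 (limma adjusted p = 1.05e-06). Of 18 measured intestinal crypt and stem cell genes, 5 fell, 1 rose and 12 did not pass, with a mean of -0.47 (camera adjusted p = 0.0307, and adjusted p = 0.0822 with an estimated correlation). The crypt genes that fell included ASCL2, a stem cell transcription factor, at -1.33 ± 0.18, CDCA7 at -1.61 ± 0.16 and the ion transporter gene SLC12A2 at -1.31 ± 0.21. Of 21 genes of the Wnt pathway machinery, 2 rose, TCF7L2 among them, and 4 fell, such as the co-repressor gene TLE1 at -0.78 ± 0.21 (camera adjusted p = 0.24 for the list).

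All 17 measured ribosome biogenesis genes fell in LS174T, with a mean log2 change of -0.95 (camera adjusted p = 1.33e-16). They included UTP20 at -1.69 ± 0.12 and RRS1 at -1.42 ± 0.15. Of 19 DNA replication genes, 17 fell and none rose, with a mean of -0.83 (camera adjusted p = 2.91e-14), among them the helicase subunit gene MCM6 at -1.40 ± 0.22 and the thymidylate synthase gene TYMS at -1.35 ± 0.16. Of 18 mitosis genes, 17 fell and none rose, also with a mean of -0.83 (camera adjusted p = 1.25e-14), among them the spindle checkpoint gene BUB1B at -1.18 ± 0.11 and BIRC5 at -1.04 ± 0.11. Of 15 p53 target genes, 4 rose and 1 fell, and the list did not pass (camera adjusted p = 0.0717). CDKN1A and the kinase gene PLK3, at 1.30 ± 0.25, were among those that rose.

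Of 13 unfolded protein and amino acid stress genes, 10 rose and none fell, with a mean log2 change of 1.27 (camera adjusted p = 7.33e-09). The stress transcription factor gene DDIT3 rose by 2.34 ± 0.53 and the endoplasmic reticulum chaperone gene DNAJB9 by 2.08 ± 0.09. Of 12 cholesterol synthesis genes, 7 rose and none fell, with a mean of 0.53 (camera adjusted p = 0.000343, and adjusted p = 0.127 with an estimated correlation). INSIG1, a sterol sensor, rose by 1.49 ± 0.21 and the synthase gene HMGCS1 by 1.22 ± 0.13. Of 17 interferon response genes, 5 rose and none fell, with a mean of 0.58 (camera adjusted p = 0.00757, and adjusted p = 0.413 with an estimated correlation), led by RSAD2 at 2.90 ± 0.34 and IFIT1 at 2.24 ± 0.40. Of 10 immediate early genes, 5 rose and none fell, with a mean of 0.67 (camera adjusted p = 0.00475, and adjusted p = 0.392 with an estimated correlation), including FOSB at 2.27 ± 0.36 and DUSP1 at 1.42 ± 0.09.

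Differentiation markers of the intestine went both ways in LS174T. Of 22 enterocyte and colonocyte genes, 3 rose and 2 fell (camera adjusted p = 0.392 for the list). The guanylin gene GUCA2A rose by 1.40 ± 0.24 and the adhesion gene CEACAM1 by 1.14 ± 0.14, while the fatty acid binding protein gene FABP2 fell by 1.18 ± 0.19 and the keratin gene KRT20 by 0.59 ± 0.16. Of 18 goblet and secretory genes, 2 rose and 1 fell (camera adjusted p = 0.231), with KLF4 at 0.50 ± 0.13 and the mucin glycosyltransferase gene GALNT12 at -1.11 ± 0.14. The mucin gene MUC2 was higher on every LS174T dnTCF4 array than on every control, at a log2 change of 0.57, but was not called. Its spread is shared with HepG2, where the dnTCF4 arrays differed widely for MUC2. The list of stromal, endothelial and immune markers had a mean of 0.42 (camera adjusted p = 0.0307, and adjusted p = 0.392 with an estimated correlation), and 1 of its 13 genes passed, the lysosomal glycoprotein gene CD68, which rose 12.5-fold, from 402 ± 5.48 to 5045 ± 245.7 intensity units (SD, n = 3). The remaining 12 of those markers did not pass the test.

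Liver lists and metabolic lists did not pass in LS174T except for cholesterol synthesis. Of 15 pericentral hepatocyte genes, 2 rose and 1 fell (camera adjusted p = 0.117), with the xenobiotic enzyme gene CYP1A1 at 2.32 ± 0.12, the glutamine synthetase gene GLUL at 0.45 ± 0.13 and AHR at -0.40 ± 0.10. Of 11 periportal hepatocyte genes, 1 fell (camera adjusted p = 0.718), and of 14 glucose metabolism genes, 3 fell (camera adjusted p = 0.463, mean -0.11 and median 0.0039). The gluconeogenic enzyme gene FBP1, on both lists, changed by -0.65 ± 0.15, and the insulin receptor substrate gene IRS1 by -0.92 ± 0.20. Of 20 hepatocyte secreted protein genes, 2 rose (camera adjusted p = 0.218), SERPINA1 by 0.58 ± 0.10 and AHSG by 0.28 ± 0.09. None of 12 bile acid genes passed (camera adjusted p = 0.0814), and the member with the smallest p, CYP7A1, measured 0.32 ± 0.12 (limma adjusted p = 0.0785). Of 8 fatty acid synthesis genes, 2 fell (camera adjusted p = 0.238), ACACA by 0.51 ± 0.11 and FASN by 0.46 ± 0.09. Of 11 BMP and TGF-beta response genes, 1 rose and 1 fell (camera adjusted p = 0.685), SKIL at 1.01 ± 0.08 and ID2 at -0.76 ± 0.09.

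Among all genes, the 6 largest rises in LS174T whose dnTCF4 arrays all lay above the controls were those of LPAR6, a lysophosphatidic acid receptor, CD68, AQP3, a water and glycerol channel, TGM2, a transglutaminase, FAXDC2 and TMEM40, with log2 changes of 4.81 ± 0.48, 3.65 ± 0.09, 3.53 ± 0.44, 3.43 ± 0.16, 3.34 ± 0.36 and 3.34 ± 0.71. The 6 largest falls were those of LGR5, CRTAM at -3.34 ± 0.10, IQGAP2 at -3.30 ± 0.09, the receptor tyrosine kinase gene KIT at -3.23 ± 0.20, AXIN2, and IGFL2 at -2.81 ± 0.14. Limma called 1553 genes higher and 2450 lower in dnTCF4 cells, 4003 in all, and 637 and 1395 of them changed at least 1.5-fold. The groups did not overlap for 41.4% of all genes, where chance gives 10%. Adjusted over the list alone, the counts of called members were the same except 1 higher for the hepatocyte secreted proteins, 3 lower for fatty acid synthesis, 18 lower for DNA replication and for mitosis, 5 higher for p53 targets and 6 higher for the interferon response. With an estimated correlation, 5 of the 10 list calls held, those of Wnt targets (adjusted p = 0.0197), DNA replication, mitosis and ribosome biogenesis (adjusted p = 0.0104 for each) and the stress response (adjusted p = 0.0315). AHSG (0.147), GLUL (0.0992), TLE1 (0.0546) and KRT20 (0.0852) lost their calls when single arrays were left out, at these highest limma adjusted p, and AHR (0.0624) and AHSG (0.116) lost theirs after quantile normalization. The crypt list lost its call with the dim filter (camera adjusted p = 0.0648) or without LS174T control replicate 2 (0.0614), and the stromal list after quantile normalization (0.11) or without LS174T control replicate 2 (0.0578) or dnTCF4 replicate 2 (0.0825).

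The comparison within HepG2 asked the same of liver cancer cells. LGR5 fell 4.51-fold, from 3859 ± 74.9 to 880 ± 241.9 intensity units (SD, n = 4), a log2 change of -2.17 ± 0.15 (limma adjusted p = 2.73e-07). AXIN2 fell 4.38-fold, a log2 change of -2.13 ± 0.27 (limma adjusted p = 5.5e-05). The gluconeogenic enzyme gene PCK1 rose 10.1-fold, from 309 ± 23.2 to 3173 ± 693 (SD, n = 4), while the drug-metabolizing enzyme gene CYP3A4, a pericentral hepatocyte marker, fell by 2.42 ± 0.18 (limma adjusted p = 4.19e-07). MYC measured -0.37 ± 0.18 and did not pass (limma adjusted p = 0.112). Genes of mitosis and DNA replication fell together.

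The HepG2 dnTCF4 arrays formed 2 pairs. The SD over genes of the log2 difference was 0.156 to 0.18 within the pair of replicates 1 and 2 and the pair of replicates 3 and 4, and 0.57 to 0.635 between arrays of different pairs, about as large as the 0.542 to 0.635 between control and dnTCF4 arrays. Among the controls it was 0.133 to 0.153 within these pairs of numbers and 0.166 to 0.178 across them. TCF7L2 changed by 2.28 in replicates 1 and 2 and by 2.96 in replicates 3 and 4, and MYC by 0.14 and -0.88 (log2, dnTCF4 against control with the same numbers). Over all genes the changes in these pairs correlated with r = 0.449 across genes, which are not independent replicates. A fit over the averaged pairs, chosen after the pairs were seen, treats HepG2 as having 2 samples per arm. Its counts of called list members stand in parentheses after the main ones below.

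Of the 17 Wnt target genes, 12 (11) fell, 1 (0) rose and 4 did not pass in HepG2, with a mean log2 change of -1.15 (camera adjusted p = 7.06e-08), at -1.36 in replicates 1 and 2 and -0.95 in replicates 3 and 4. The Wnt antagonist gene DKK4 fell by 2.94 ± 0.12 (limma adjusted p = 9.17e-09) and the receptor gene TNFRSF19 by 2.06 ± 0.40 (limma adjusted p = 0.00128). Of 18 crypt and stem cell genes, 8 (6) fell and 4 (1) rose, with a mean of -0.39 (camera adjusted p = 0.0253, and adjusted p = 0.114 with an estimated correlation). CDCA7 fell by 1.39 ± 0.14 and the transcription factor gene PROX1 by 0.86 ± 0.12. Of 21 Wnt machinery genes, 8 (2) rose and 5 (1) fell (camera adjusted p = 0.677, mean 0.14 and median -0.017), and among those that rose was the co-activator gene BCL9L at 1.004 ± 0.15.

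Hepatocyte genes with a place in the liver lobule changed in both directions. Of 15 pericentral genes, 7 (7) fell and 3 (2) rose, with a mean of -0.57 (camera adjusted p = 0.00637, and adjusted p = 0.138 with an estimated correlation). With CYP3A4 fell the glutamate transporter gene SLC1A2 at -2.41 ± 0.19, RGN at -2.03 ± 0.17 and the ammonium transporter gene RHBG at -1.26 ± 0.14. Of 11 periportal genes, 4 (3) rose and 4 (3) fell, and the list mean of 0.014 turned to -0.051 under quantile normalization and -0.054 under median centring (camera adjusted p = 0.677 as deposited). PCK1, on that list and on that of glucose metabolism, rose by 3.33 ± 0.14, and the iron hormone gene HAMP fell by 2.38 ± 0.47. Of 14 glucose metabolism genes, 3 (3) rose and 4 (2) fell (camera adjusted p = 0.677, mean -0.048 and median 0.032), including the glucose transporter gene SLC2A2 at -2.64 ± 0.36. Of 20 hepatocyte secreted protein genes, 6 (3) fell and none (0) rose, with a mean of -0.34 (camera adjusted p = 0.000816, and adjusted p = 0.185 with an estimated correlation). The apolipoprotein gene APOC3 fell by 0.92 ± 0.10, and haptoglobin, HP, by 2.13 ± 0.71, at -3.82 in replicates 1 and 2 and -0.45 in replicates 3 and 4.

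Of 12 bile acid genes in HepG2, 3 (1) rose and 5 (5) fell (camera adjusted p = 0.101), with the canalicular transporter gene ABCB4 at -2.04 ± 0.15 and the basolateral transporter gene SLC51A at 1.498 ± 0.13. Of 12 cholesterol synthesis genes, 8 (2) fell and 2 (0) rose, with a mean of -0.30 (camera adjusted p = 0.00353, and adjusted p = 0.196 with an estimated correlation), STARD4 by 0.90 ± 0.13 and LSS by 0.69 ± 0.14 among those that fell. Of 8 fatty acid synthesis genes, 1 (1) rose and 3 (0) fell (camera adjusted p = 0.367), with THRSP at 0.90 ± 0.12 and SCD at -0.38 ± 0.10. Of 22 enterocyte genes, 8 (6) rose and 3 (2) fell (camera adjusted p = 0.485), among them the intestinal alkaline phosphatase gene ALPI at 1.93 ± 0.50, the apolipoprotein gene APOA4 at 1.78 ± 0.14, CA2 at 1.46 ± 0.21 and FABP2 at -1.37 ± 0.17. Of 18 goblet and secretory genes, 5 (2) rose and none (0) fell (camera adjusted p = 0.61), with the mucin gene MUC2 at 1.36 ± 0.37 and TFF1 at 0.63 ± 0.12. Of the 13 stromal, endothelial and immune markers, 7 (1) rose (camera adjusted p = 0.0828), CD68 by 0.70 ± 0.08 and DCN by 0.59 ± 0.18.

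Of the 18 mitosis genes, 17 (15) fell and none (0) rose in HepG2, with a mean of -1.02 (camera adjusted p = 2.47e-15), among them the kinase gene CDK1 at -2.48 ± 0.40 and BUB1B at -1.57 ± 0.09. Of 19 DNA replication genes, 15 (12) fell and 1 (0) rose, with a mean of -0.64 (camera adjusted p = 3.73e-09), including MCM6 at -1.26 ± 0.19 and CDC6 at -1.17 ± 0.20. Of 17 ribosome biogenesis genes, 11 (3) fell and none (0) rose, with a mean of -0.28 (camera adjusted p = 0.000116, and adjusted p = 0.135 with an estimated correlation), including DKC1 at -0.73 ± 0.09 and MYBBP1A at -0.58 ± 0.10. Of 15 p53 targets, 6 (2) rose and 2 (0) fell (camera adjusted p = 0.485), with PLK3 at 1.41 ± 0.21 and CDKN1A at 0.92 ± 0.13. The p53 mean was -0.11 in replicates 1 and 2 only (camera adjusted p = 0.118) and 0.75 in replicates 3 and 4 only, where the list passed (camera adjusted p = 0.000133).

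Of 17 interferon response genes in HepG2, 10 (7) fell and 3 (2) rose, with a mean of -0.81 (camera adjusted p = 0.00023, and adjusted p = 0.313 with an estimated correlation), at -0.38 in replicates 1 and 2 and -1.25 in replicates 3 and 4. IFIT2 fell by 2.47 ± 0.20 and OASL by 1.96 ± 0.17. Of 10 immediate early genes, 7 (4) rose and none (0) fell, with a mean of 0.92 (camera adjusted p = 0.00573, and adjusted p = 0.415 with an estimated correlation), at 0.39 and 1.44 in the respective pairs, FOSB by 2.23 ± 0.32 and FOS by 1.32 ± 0.41. Of 13 stress response genes, 3 (2) rose and 2 (1) fell (camera adjusted p = 0.787, mean 0.12 with a camera direction downward), with SESN2 at 1.23 ± 0.12 and TRIB3 at 0.78 ± 0.14. Of 11 BMP and TGF-beta response genes, 2 (0) rose and 4 (3) fell (camera adjusted p = 0.0731), with BAMBI at -1.34 ± 0.20 and SMAD9 at -1.21 ± 0.13.

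**Figure D2:**
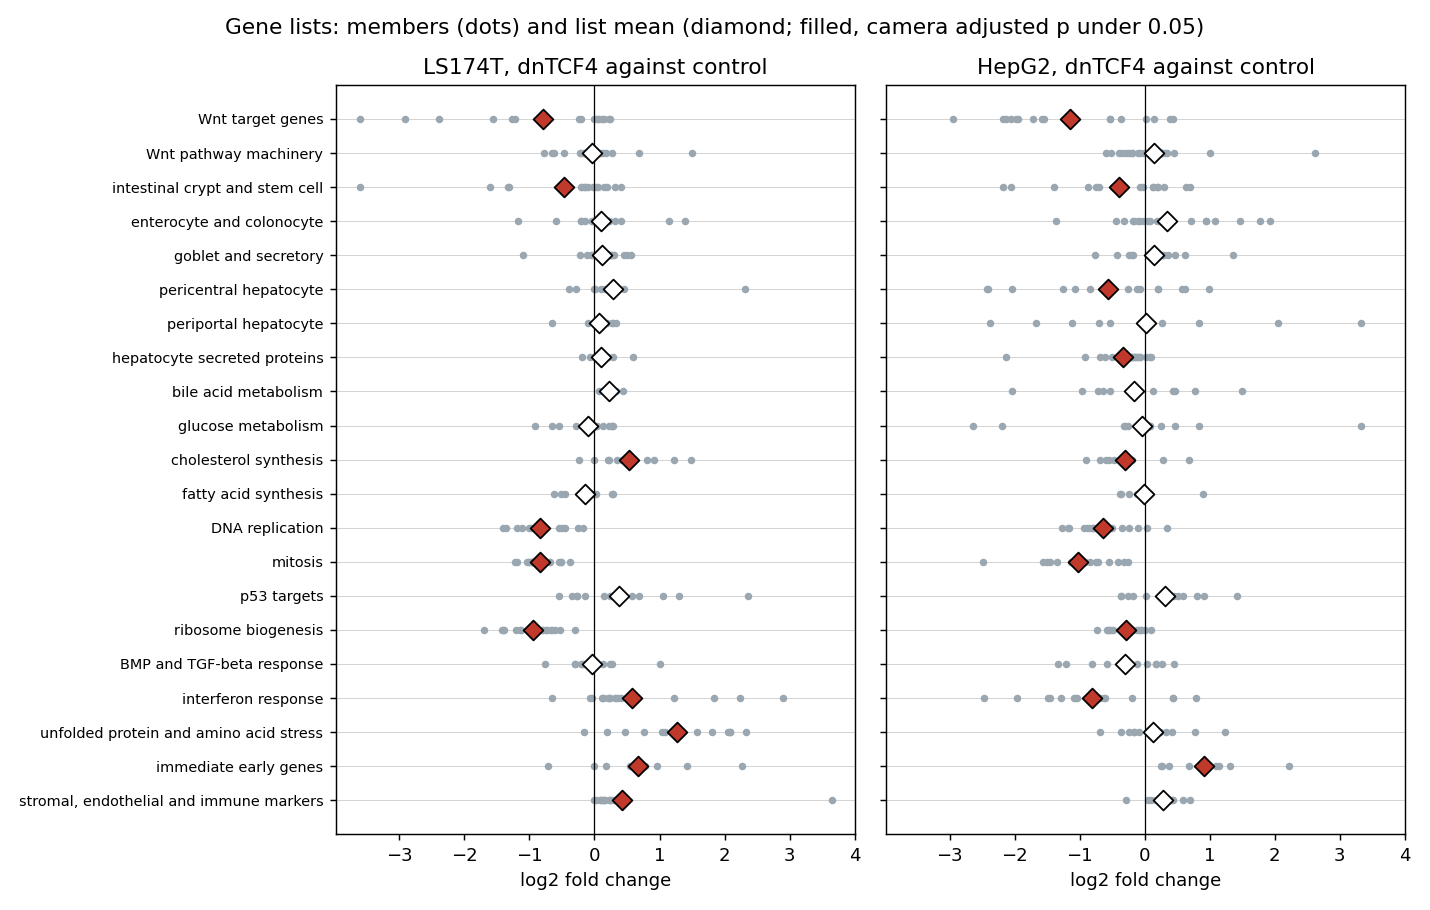
Log2 fold change of dnTCF4 against control for the measured members (dots) of 21 gene lists in LS174T (left) and HepG2 (right), with the list mean as a diamond, filled where camera's adjusted p was under 0.05. The means of Wnt target, DNA replication, mitosis and ribosome biogenesis genes lay below 0 in both lines, and that of the interferon response was 0.58 in LS174T and -0.81 in HepG2.

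Small RNAs were left out of the genes named here, and MIR30A, at -4.71, fell furthest of all called genes whose HepG2 arrays did not overlap. The 6 largest rises in HepG2 were those of the lipid transporter gene MFSD2A at 3.39 ± 0.24, PCK1, HAVCR1 at 3.20 ± 0.22, PAEP at 3.19 ± 0.10, the lipoxygenase gene ALOX5 at 2.87 ± 0.91 and PTAFR at 2.83 ± 0.39. The 6 largest falls after MIR30A were those of the amino acid transporter gene SLC6A14 at -4.20 ± 0.53, the alcohol dehydrogenase genes ADH6 at -3.43 ± 0.60 and ADH4 at -3.30 ± 0.29, SERPINA7 at -3.38 ± 0.76, CPB2 at -3.28 ± 0.73 and ERP27 at -3.26 ± 0.21. Of the 58 called genes named for HepG2, 16 had changes over 1.5 apart (log2) between the pairs, so their mean describes neither pair. In replicates 1 and 2 and in replicates 3 and 4, PTAFR measured 1.79 and 3.87, ALPI 0.69 and 3.16, MUC2 0.42 and 2.29, FOS 0.37 and 2.26, and FOSB 1.42 and 3.04. SLC6A14 measured -5.55 and -2.86, ADH6 -5.04 and -1.82, SERPINA7 -5.29 and -1.46, CPB2 -5.16 and -1.41, and ADH4 -4.11 and -2.49. HAMP measured -3.61 and -1.16, SLC2A2 -3.52 and -1.76, TNFRSF19 -3.11 and -1.01, CDK1 -1.53 and -3.43, and HP the values above. ALOX5, the last of them, measured 0.57 in replicates 1 and 2 and 5.17 in replicates 3 and 4, and did not pass over averaged pairs (limma adjusted p = 0.0866). Limma called 5408 genes higher and 3052 lower, 8460 in all, and 1185 and 1511 of them changed at least 1.5-fold. Of the called genes, 63.92% were higher, against 51.91% after quantile normalization (3258 higher and 3018 lower) and 52.35% after median centring (3919 and 3567). Over averaged pairs, 1396 genes were higher and 1568 lower, all 2964 of them called in the same direction with single arrays. The groups did not overlap for 44.2% of genes, where chance gives 2.86% with single arrays as samples and 33.3% with pairs as samples. Adjusted over the list alone, the counts of called members were the same except 2 higher for Wnt targets, 4 higher for goblet genes, 4 lower for hepatocyte secreted proteins, 9 lower for cholesterol synthesis, 18 lower for mitosis and 8 higher for immediate early genes. With an estimated correlation, the Wnt target (adjusted p = 0.00455), mitosis (adjusted p = 0.0123) and DNA replication (adjusted p = 0.0303) lists held their calls. HP, MUC2, SCD, FOS and DCN also did not pass over averaged pairs (limma adjusted p = 0.115, 0.0592, 0.148, 0.0847 and 0.143). In replicates 1 and 2 only, the crypt, pericentral, interferon and immediate early lists did not pass (camera adjusted p = 0.0878, 0.0707, 0.0525 and 0.111).

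The 2 responses were then set against each other by a test of the difference of the changes, LS174T minus HepG2. The largest positive difference was that of LPAR6, at 6.20 ± 0.64 (limma adjusted p = 2.47e-05), which rose from 47.3 ± 8.35 to 1352 ± 214.2 intensity units in LS174T (SD, n = 3) and measured 1761 ± 77.3 and 857 ± 615.1 in HepG2 (SD, n = 4). Its HepG2 dnTCF4 arrays measured 330 and 319 in replicates 1 and 2 and 1364 and 1415 in replicates 3 and 4, so their mean describes neither pair. All 3 LS174T controls lay below their array's lower quartile for LPAR6, as they did for IFIT2 and RSAD2, so the size of these differences is uncertain. The interferon response genes IFIT2 and RSAD2 differed by 4.30 ± 0.31 (limma adjusted p = 1.07e-06) and 3.96 ± 0.44 (limma adjusted p = 4.81e-05). The largest negative differences included MFSD2A at -3.72 ± 0.37, KIT at -3.67 ± 0.26 and PCK1 at -3.29 ± 0.21. Every HepG2 control lay below its array's lower quartile for KIT, where a fall would hardly be seen. LGR5 fell further in LS174T, by a difference of -1.44 (limma adjusted p = 0.000764), while the AXIN2 difference of -0.79 did not pass (limma adjusted p = 0.22). The MYC difference of -0.90 passed (limma adjusted p = 0.045) but not over averaged HepG2 pairs (limma adjusted p = 0.117). The Wnt target list as a whole did not pass (camera adjusted p = 0.0829, and adjusted p = 0.175 with an estimated correlation). Its mean was 0.36, with 6 members higher and 3 lower, or 3 higher and 2 lower over averaged HepG2 pairs. DKK4, at 3.07, was among the higher ones, but it was dim in LS174T, at 143 to 200 intensity units, which left little room for a fall. With HepG2 replicates 1 and 2 only the list's mean was 0.57 and passed (camera adjusted p = 0.0432). With replicates 3 and 4 only it did not pass, the mean change of the list being -0.95 in that HepG2 pair and -0.79 in LS174T.

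MIR30A, likewise left out, differed by 5.14. The remaining largest positive differences were those of SLC6A14 at 4.44 ± 0.80, GREB1 at 3.86 ± 0.33 and ADH6 at 3.75 ± 0.91. The remaining negative ones were those of CRTAM at -3.22 ± 0.13, NMU at -3.03 ± 0.18 and HAVCR1 at -2.95 ± 0.33. SLC6A14, ADH6 and HAVCR1 in LS174T and CRTAM in HepG2 lay below the lower quartile on every array of that line, where a fall would hardly be seen. NMU in HepG2, at 123 to 190 intensity units, lay near that bound. Of the 21 lists, 7 differed between the lines. The changes are compared here, not the levels. The mean change of the stress response list was higher in LS174T by 1.15 (camera adjusted p = 5.5e-09, 9 members higher). That of cholesterol synthesis was higher by 0.84 (camera adjusted p = 8.65e-09, 9 members higher) and that of pericentral genes by 0.84 (camera adjusted p = 2.49e-06, 7 members higher and 1 lower). The pericentral members RGN and SLC1A2 were dim in LS174T, at 135 to 203 intensity units, which left little room for a fall. The mean change of ribosome biogenesis genes was lower, at a difference of -0.67 (camera adjusted p = 8.66e-09, 12 members lower). With an estimated correlation these 4 held, each with an adjusted p = 0.0308. The interferon response differed by 1.40 with 8 members higher (camera adjusted p = 6.37e-08, and adjusted p = 0.175 with an estimated correlation), hepatocyte secreted proteins by 0.44 with 5 higher (camera adjusted p = 1.53e-05, and adjusted p = 0.126 with an estimated correlation) and bile acid genes by 0.39 with 5 higher and 1 lower (camera adjusted p = 0.00574, and adjusted p = 0.196 with an estimated correlation). Adjusted over the list alone, these counts were 10 higher for the stress response, 10 for cholesterol synthesis, 8 for pericentral genes and 6 for bile acid genes, 10 higher and 1 lower for the interferon response, 15 lower for ribosome biogenesis, and unchanged for secreted proteins. Limma called 1340 genes with a higher and 1608 with a lower change in LS174T, or 45.45% higher, against 54.5% after quantile normalization (1642 and 1371) and 59.89% after median centring (1650 and 1105). Over averaged HepG2 pairs the counts were 610 and 538. Within the lists, that fit called 6 higher for the stress response, 6 for cholesterol synthesis, 7 for the interferon response and 1 for secreted proteins. It called 7 higher and 1 lower for pericentral genes, 4 higher and 1 lower for bile acid genes and 5 lower for ribosome biogenesis. The bile acid list lost its call with the dim filter and with HepG2 replicates 1 and 2 only (camera adjusted p = 0.172 and 0.0738).

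Many genes moved the same way in both lines. LGR5, AXIN2, RNF43, CDCA7, MCM6 and BUB1B fell in each, and TGM2, FOSB, PLK3 and CDKN1A rose in each. In all, 1299 genes fell in both lines, where independent lists would share 406 (odds ratio 9.15, 95% interval 8.32 to 10.1 by Fisher's exact test, two-sided). Another 755 rose in both, where independent lists would share 456 (odds ratio 2.48, 95% interval 2.23 to 2.76), and 345 were called in opposite directions, 147 of them higher in LS174T and 198 higher in HepG2. The intervals take genes as independent, which they are not. Both sets of calls also share each gene's estimate of the spread, so genes with little spread are more readily called in both lines. Over averaged HepG2 pairs 718 fell and 311 rose in both. The log2 changes correlated with r = 0.398 (Spearman's rho 0.402) across 18417 genes, at r = 0.29 for HepG2 replicates 1 and 2 and 0.386 for replicates 3 and 4, and genes are not independent replicates. The lines share no control arrays.

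**Figure D3:**
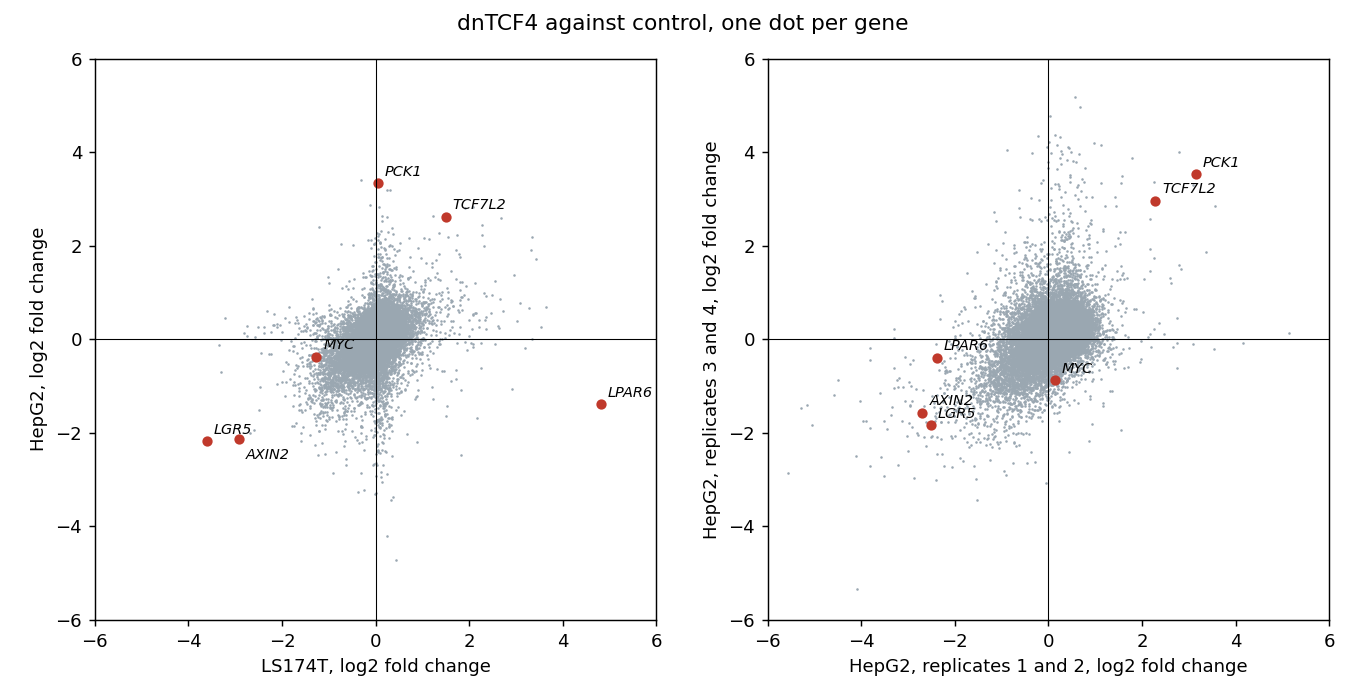
Log2 fold change of dnTCF4 against control, 1 dot per gene, for HepG2 against LS174T (left) and for HepG2 replicates 3 and 4 against replicates 1 and 2 (right), with 6 genes named in red. LPAR6 rose by 4.81 in LS174T, PCK1 by 3.33 in HepG2, and the correlation across genes was 0.398 on the left and 0.449 on the right.

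The control cells of each line were compared to show where the 2 responses started. The liver secreted protein genes AFP and AHSG were lower in LS174T by log2 changes of -7.34 ± 0.10 (limma adjusted p = 2.81e-15) and -6.92 ± 0.08 (limma adjusted p = 2.02e-15), with AFP at 67.9 ± 10.9 intensity units in LS174T (SD, n = 3) and 11108 ± 324.1 in HepG2 (SD, n = 4). Every LS174T control lay below its array's lower quartile for AFP, AHSG and CYP3A4, and every HepG2 control for CD3E, so the size of these differences is uncertain. All 20 hepatocyte secreted protein genes were lower in LS174T, with a mean of -5.38 (camera adjusted p = 1.45e-13, and adjusted p = 0.0336 with an estimated correlation). Among intestinal genes, CD44 was higher in LS174T by 3.89 ± 0.08 and the secretory gene AGR2 by 3.23 ± 0.44, while ANPEP at -4.65 ± 0.09, CEACAM1 at -4.62 ± 0.13, PROX1 at -3.25 ± 0.13 and the lysozyme gene LYZ at -6.81 ± 0.12 were lower. The liver zonation genes CYP3A4, RGN, CPS1 and HAMP were lower in LS174T by -3.38 ± 0.19, -3.11 ± 0.18, -3.44 ± 0.15 and -3.01 ± 0.50.

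Of 18 crypt genes, 8 were higher and 6 lower in LS174T, and of 22 enterocyte genes 6 were higher and 6 lower (camera adjusted p = 0.534 and 0.994). Of 13 stromal, endothelial and immune markers, 5 were higher, such as CD3E at 2.35 ± 0.17, and 4 lower, such as CD68 at -3.00 ± 0.08 (camera adjusted p = 0.906). The p53 target list, with 13 of 15 members lower (camera adjusted p = 0.0021, and adjusted p = 0.57 with an estimated correlation), and cholesterol synthesis, with 10 lower and 1 higher (camera adjusted p = 0.0116, and adjusted p = 0.547 with an estimated correlation and 0.0827 with the dim filter), were the other lists that passed, and for these 3 lists counts adjusted over the list alone were the same. Limma called 5173 genes higher and 7049 lower in LS174T, or 42.33% higher, against 52.65% after quantile normalization (6180 and 5557). Quantile normalization and median centring moved the median of all genes by 0.115 and 0.13 on the log2 scale here, and cell line and any array batch cannot be told apart in this comparison.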

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

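Of the tests below, those of LS174T cells in a HepG2 pair, of the dnTCF4 level, of the scaling behind the excess of HepG2 rises, of the narrower intensity distribution and of the splits of averaged pairs were chosen after the result was seen. The others were written down before it.

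Some named genes and lists passed a test for a difference between the lines. The test of the difference of the changes (LS174T minus HepG2, log2, limma adjusted p at most 0.0488) passed for 71 of the 103 genes named within a line or for the difference. Most of these were picked for a large change or difference on the same arrays, so this share says nothing about genes at large. Among all 18417 genes, 2948 passed (16.01%). Over averaged HepG2 pairs 52 of the 71 passed. The other 19 did not, at limma adjusted p from 0.0567 to 0.191: AHSG, BAMBI, DKC1, DUSP1, FBP1, HAMP, ID2, IRS1, KRT20, MYBBP1A, MYC, RRS1, SCD, SERPINA1, SERPINA7, SESN2, SLC12A2, TFF1 and THRSP. Positive differences among interferon response genes were IFIT2 4.30, RSAD2 3.96, IFIT1 2.86 and OASL 2.32. Among hepatocyte, bile acid and transporter genes they were SLC6A14 4.44, ADH6 3.75, SERPINA7 3.74, ADH4 3.28, SLC2A2 2.65, SLC1A2 2.64, HAMP 2.57, CYP3A4 2.51, ABCB4 2.22, RGN 2.19, CYP1A1 1.33, GLUL 1.29, RHBG 1.27, APOC3 1.13, CYP7A1 0.86, SERPINA1 0.66 and AHSG 0.49. Among stress, sterol and fatty acid synthesis genes they were DNAJB9 2.17, HMGCS1 1.51, STARD4 1.11, SCD 0.65 and SESN2 0.58. The other positive differences were LPAR6 6.20, GREB1 3.86, FAXDC2 3.34, AQP3 3.26, CD68 2.95, ERP27 2.90, TGM2 1.72, CDKN1A 1.44, SMAD9 1.45, CEACAM1 1.30, BAMBI 1.03, SKIL 0.98 and DUSP1 0.57. For FAXDC2, AQP3 and IRS1, among other genes, the HepG2 pairs moved in opposite directions, so the mean HepG2 change describes neither pair. FAXDC2 measured 705 and 650 in dnTCF4 replicates 1 and 2 and 2025 and 1990 in replicates 3 and 4, against 1114 to 1223 in controls. AQP3 measured 1403 and 1397, then 5402 and 5262, against 2204 to 2386. IRS1 measured 729 and 666, then 391 and 431, against 512 to 650. IFIT1 was lower in replicates 3 and 4 only, at 1559 and 1084, then 372 and 441, against 1081 to 1138.

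Wnt target and crypt genes went both ways, with DKK4 3.07, PROX1 0.92, LEF1 -2.53, ASCL2 -1.45, LGR5 -1.44, SLC12A2 -0.90 and MYC -0.90, and TCF7L2 itself differed by -1.12. The Wnt target list had a mean difference of 0.36 and did not pass (camera adjusted p = 0.0829). Negative differences among ribosome biogenesis genes were UTP20 -1.15, RRS1 -0.90, DKC1 -0.68 and MYBBP1A -0.63. The other negative differences were MFSD2A -3.72, KIT -3.67, PCK1 -3.29, CRTAM -3.22, NMU -3.03, HAVCR1 -2.95, IGFL2 -2.95, PAEP -2.89, IQGAP2 -2.60, APOA4 -1.82, CA2 -1.61, GALNT12 -1.58, SLC51A -1.21, AHR -1.02, KRT20 -0.88, IRS1 -0.83, FBP1 -0.72, TFF1 -0.69, ID2 -0.64 and THRSP -0.62. The lists that differed, as mean differences, were the interferon response 1.40, unfolded protein and amino acid stress 1.15, pericentral hepatocyte 0.84, cholesterol synthesis 0.84, hepatocyte secreted proteins 0.44, bile acid metabolism 0.39 and ribosome biogenesis -0.67. With an estimated correlation the interferon response, secreted protein and bile acid lists lost their calls (camera adjusted p = 0.175, 0.126 and 0.196). Low signal limits some of these values, by a bound chosen after they were seen. ADH6, AHSG, CYP3A4, HAVCR1, SERPINA7 and SLC6A14 lay below the array's lower quartile on every LS174T array, and CRTAM on every HepG2 array, where a fall would hardly be seen. For those of them that fell in the other line, ADH6, AHSG, CYP3A4, SERPINA7, SLC6A14 and CRTAM, the difference does not show that the gene responds differently where it is expressed. The controls of LS174T lay there for IFIT1, IFIT2, LPAR6 and RSAD2 and those of HepG2 for KIT and LEF1, as did HepG2 dnTCF4 for CYP7A1. KIT and LEF1 fell in LS174T, and a fall from so low in HepG2 would hardly be seen, so the same limit holds for them. ADH4, SLC2A2, SLC1A2 and RGN in LS174T, at 109 to 203 intensity units, lay near the lower quartiles, as did NMU in HepG2, at 123 to 190. They fell in the other line, so the same limit holds for them. Members below the quartile on every LS174T array numbered 7 of 20 secreted protein genes, 2 of 15 pericentral genes and 1 of 17 interferon response genes, and the other members had mean differences of 0.485, 0.75 and 1.42. Among those other members, 2 secreted protein genes were called higher, 6 pericentral genes higher and 1 lower, and 7 interferon response genes higher. RGN and SLC1A2 were among these pericentral genes, so low signal still limits that result.

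A single control array stood apart from the other 3 HepG2 controls for 6 named genes. The gap to the nearest other array, as a share of the group's range, exceeded Dixon's 95% critical value. The shares were AHSG at 0.917 and UTP20 at 0.834 (replicate 3), CD44 at 0.87, INSIG1 at 0.857 and ALOX5 at 0.836 (replicate 1), and TLE1 at 0.841 (replicate 2). There were 222 such tests over the HepG2 control and dnTCF4 arrays, and chance alone flags about 1 in 20 of separate samples. Where the dnTCF4 arrays stood in 2 tight pairs, the large gap lay in the middle and a flag was hardly possible. That rate therefore does not hold for all 222. Among 13792 probe sets with no or several gene symbols, which entered only the alternative with all probe sets, 713 passed the threshold in LS174T (278 higher, 435 lower) and 2982 in HepG2 (1350 higher, 1632 lower).

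The first pattern is that the 4 HepG2 dnTCF4 arrays fell into 2 pairs. LS174T cells in 1 pair would carry their abundant transcripts with them, yet 172 genes at least 8-fold brighter in LS174T controls had a median log2 difference of 0.129 between the pairs, under the bound of 0.2. Array-wide scaling or distribution is argued against as well, since the SD over genes of the difference between pair means was 0.558 after quantile normalization and 0.589 before it, against 0.15 and 0.163 within the pairs after it. More dnTCF4 in replicates 3 and 4, where TCF7L2 was brighter, would have lowered Wnt targets further. The 12 fallen targets instead changed by 0.629 ± 0.29 (SE over genes) less in them, narrowly past 2 SE and over genes only. They were picked as called lower on these same arrays, which leaves out MYC, a target lower only in replicates 3 and 4. NOTUM, at -3.06 in replicates 1 and 2 and -0.37 in replicates 3 and 4, differed most. The result therefore does not decide about the dnTCF4 level. A difference in transfection, sorting or array batch between the pairs remains open and untested, since the labels name none, and no biological explanation was tested.

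The second pattern is the excess of rises in HepG2. Among called genes 63.92% were higher as deposited and 51.91% after quantile normalization, which is what scaling between the arrays would give, so the excess may come from the authors' normalization. A true excess of small rises cannot be excluded, because quantile normalization removes a shared shift whatever its source. At a change of at least 1.5-fold, lower genes outnumbered higher ones, 1511 against 1185.

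The third pattern is the joint fall of ribosome biogenesis, DNA replication and mitosis genes in LS174T. A narrower intensity distribution on dnTCF4 arrays is argued against, since the mean log2 change of the 54 genes was -0.81 after quantile normalization and -0.87 before. Their brightness does not account for it either: 0 of 10000 lists matched on mean log2 value had a median as low as theirs, -0.86, the lowest being -0.34. A response of the cells to dnTCF4 is one hypothesis left, and a difference in density or stress between the sorted populations is another, untested here.

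Other splits of the same arrays bear on whether the counts could be chance. For LS174T, 1 of the 10 splits, the real one, gave as many genes (4003, the highest other split giving 0), and 10 splits are too few for a share under 0.05. For HepG2, 1 of 35 splits did, the real one with 8460 genes, and the highest other gave 1 gene. Those splits take the arrays as separate samples, which the tight pairs of dnTCF4 arrays put in doubt. With averaged pairs as samples, 1 of 3 splits gave as many genes, the real one with 2964 against 0 at most in the others, and 3 splits are too few for a share under 0.05. For the difference, 2 of 100 drawn splits gave as many genes, the real one with 2948 and another with 5932 that kept the HepG2 groups together and mixed those of LS174T. That split carries the whole HepG2 change, so these splits do not decide whether chance gave the difference. For the controls, 1 of 35 splits did, the real one with 12222 genes against 7549 at most in the others. That share lies under 0.05, so chance is unlikely there if the arrays are separate samples, which the labels do not state.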

How the results depend on the processing

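The following settings were chosen after the data were seen: HepG2 pairs averaged, HepG2 replicates 1 and 2 only, HepG2 replicates 3 and 4 only, a random block of HepG2 pairs and gene-by-gene array weights. The planned array weights ended with a convergence warning and gave LS174T dnTCF4 replicate 1 a weight of 0.00336 and LS174T control replicate 1 a weight of 8.66, and the gene-by-gene weights were added for that reason. Over all settings, the values of named genes kept their direction and side of the threshold in 4061 of 4124 cases, lost a call in 55, gained one in 7 and reversed in 1, and those of gene lists did so in 2401 of 2541, 29, 67 and 44. Unless a sentence says otherwise, the cause of a change was not tested. The arrays have no background measure, so dim genes limit the changes that can be seen.

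In LS174T, counts of higher and lower genes were 637 and 1395 with a 1.5-fold minimum, by construction, and 3689 and 4133 with gene-by-gene weights. Higher genes numbered 2658 with HepG2 replicates 1 and 2 only and 2537 with replicates 3 and 4 only, where the spread between HepG2 pairs no longer enters the shared estimate. In HepG2, the counts were 1185 and 1511 with the 1.5-fold minimum, 1396 and 1568 over averaged pairs and 1408 and 1826 with a random block of pairs (consensus correlation 0.801), where fewer independent samples are assumed. Higher genes numbered 3258 after quantile normalization and lower features 5059 over all probe sets, which are more numerous. For the difference, higher and lower counts were 2118 and 3369 with array weights, 3129 and 5636 with gene-by-gene weights, 610 and 538 over averaged pairs, 2672 and 3670 with replicates 1 and 2 only, and 744 and 680 with the random block. Lower counts were 987 with the 1.5-fold minimum and 2803 with replicates 3 and 4 only. Higher genes in the control comparison numbered 3046 with the dim filter, 8083 over all probe sets and 3136 with the 1.5-fold minimum.

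Genes higher in both lines, lower in both and opposite numbered 1963, 2099 and 1113 with gene-by-gene weights, 167, 536 and 47 with the 1.5-fold minimum, 311, 718 and 95 over averaged pairs, and 359, 839 and 113 with the random block. With replicates 3 and 4 only 1211 were higher in both, and opposite genes were 799 with replicates 1 and 2 only and 580 with array weights. The correlation across genes was 0.312 with array weights, 0.319 with gene-by-gene weights and 0.29 with replicates 1 and 2 only. Lists past the threshold numbered 5 in LS174T, 3 in HepG2, 4 for the difference and 1 for the controls with an estimated correlation, and 16, 15 and 17 in HepG2, the difference and the controls with fry, which asks another question. HepG2 replicates 1 and 2 only gave 6 in HepG2 and 5 for the controls, where quantile normalization gave 6 and all probe sets 8.

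The values that reversed were those of MYC in HepG2, at 0.14 with replicates 1 and 2 only, and of lists that did not pass camera as deposited, some of which passed fry. In HepG2 the periportal mean was -0.051 after quantile normalization, -0.054 after median centring, -0.069 with array weights, -0.087 with gene-by-gene weights and -0.13 with replicates 1 and 2 only. With replicates 3 and 4 only the goblet mean was -0.0085, the glucose mean 0.023 and the fatty acid mean 0.047. With replicates 1 and 2 only the p53 mean was -0.11 and the stress mean -0.087, and with gene-by-gene weights -0.021 and -0.036, the stress mean being -0.0080 with array weights. For the difference, goblet means were 0.092 after quantile normalization, 0.047 after median centring and 0.12 with replicates 3 and 4 only, where the periportal mean was -0.090 and the p53 mean -0.36. Median centring also gave 0.00021 for crypt and 0.020 for glucose genes, the dim filter -0.11 for periportal genes, and replicates 1 and 2 only 0.013 for glucose and 0.28 for immediate early genes, the latter at 0.074 with array weights and 0.13 with gene-by-gene weights. The immediate early difference passed in opposite directions in the pairs, at 0.28 with replicates 1 and 2 only (camera adjusted p = 0.0253) and -0.78 with replicates 3 and 4 only (camera adjusted p = 0.00382). The p53 difference passed with replicates 1 and 2 only (0.49, camera adjusted p = 0.000491). For the controls, quantile normalization gave 0.33 for DNA replication, 0.40 for mitosis, 0.083 for ribosome biogenesis and 0.070 for immediate early genes, and median centring 0.0034, 0.075 and 0.013 for DNA replication, mitosis and stromal markers.

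Leaving out each array in turn kept every count of genes within 1.5 times. Ranges that crossed 0 were -0.0054 to 0.13 for periportal genes in LS174T, -0.040 to 0.065 for periportal and -0.042 to 0.014 for fatty acid genes in HepG2, -0.10 to 0.024 for goblet, -0.020 to 0.12 for periportal and -0.079 to 0.21 for p53 genes in the difference, and -0.084 to 0.00053 for mitosis in the controls. Single arrays decided some named calls. MYC in HepG2 passed without dnTCF4 replicate 1 (-0.51) or replicate 2 (-0.52), ALOX5 (2.09) and FOS (0.98) were lost without dnTCF4 replicate 3, and HP was lost without any single HepG2 control or without dnTCF4 replicate 1 (-1.63) or 2 (-1.52). In LS174T, TLE1 was lost without control replicate 1 (-0.77) or 3 (-0.76) or dnTCF4 replicate 2 (-0.77), KRT20 without control replicate 1 (-0.49) or 3 (-0.49) or dnTCF4 replicate 1 (-0.51) or 2 (-0.57), and GLUL without control replicate 1 (0.43) or 2 (0.38) or dnTCF4 replicate 2 (0.37). AHSG was lost without LS174T control replicate 1 (0.23) or 3 (0.29), dnTCF4 replicate 2 (0.22) or 3 (0.26), or HepG2 control replicate 2 or 4 (0.28), and CYP7A1 passed without control replicate 3 (0.42). Lists that passed without an array were pericentral (0.36) and bile acid (0.30) genes without LS174T dnTCF4 replicate 3 and p53 targets (0.40) without control replicate 3 in LS174T, BMP and TGF-beta genes (-0.30) without LS174T control replicate 2 in HepG2, and, for the difference, mitosis (at most 0.23) without LS174T control replicate 1 or 3, LS174T dnTCF4 replicate 2 or HepG2 dnTCF4 replicate 1 or 2. Deviations of same-numbered samples from their group means correlated with 0.0708, 0.213 and 0.385 in LS174T and with -0.0078, -0.056, 0.0433 and -0.114 in HepG2. These values were not compared with those of samples with unlike numbers. All were positive in LS174T, so pairing by number is not excluded there, while in HepG2 they went both ways. With the replicate block, 1388 genes were higher and 2256 lower in LS174T, 5188 and 2933 in HepG2, and 1144 and 1310 for the difference.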

Other observations

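The hypothesis test on MYC in this part was chosen after the result was seen. The Wnt targets that fell in HepG2 did so unevenly between the pairs of arrays. All 12 are named here, chosen after their values were seen. In replicates 1 and 2 the secreted Wnt deacylase gene NOTUM changed by -3.06 (log2), TNFRSF19 by -3.11, AXIN2 by -2.70, NKD1 by -2.40 and LGR5 by -2.52, against -0.37, -1.01, -1.57, -1.57 and -1.83 in replicates 3 and 4. DKK4 changed by -3.21 and -2.68, ZNRF3, a membrane ubiquitin ligase gene, by -2.14 and -1.77, SP5 by -1.76 and -1.39, and BMP4 by -0.76 and -0.31. RNF43 at -1.25 and -1.85, the Wnt antagonist gene DKK1 at -0.65 and -1.51 and the cyclin gene CCND1 at -0.47 and -0.59 went further down in replicates 3 and 4. These differences rest on 2 arrays per pair and were not tested gene by gene.

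Genes chosen for their large HepG2 changes differed in how evenly the pairs of replicates shared them: PCK1 changed by 3.15 and 3.52 and PAEP by 3.09 and 3.29, whereas SERPINA7 changed by -5.29 and -1.46 and CPB2 by -5.16 and -1.41.

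One hypothesis was that ribosome biogenesis genes follow MYC, a known regulator of them. In LS174T both fell. In HepG2, MYC changed by 0.14 in replicates 1 and 2 and by -0.88 in replicates 3 and 4, so the list would be expected to fall further in the latter. Its 17 members instead had a mean change of -0.36 in replicates 1 and 2 and of -0.21 in replicates 3 and 4. They changed by 0.148 ± 0.0851 (SE over genes) less in replicates 3 and 4, and 11 of them fell less there. The fall in replicates 1 and 2, where MYC was not lower, argues against a fall of the MYC transcript behind it in that pair. The difference between the pairs lies within 2 SE of 0, so whether the list follows MYC otherwise stays undecided.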
